A study of Mus musculus with 9 samples.

How the data were processed

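RNA was sequenced from 9 cultures of mouse regulatory T cells, 4 Ezh2-deficient and 5 WT, per the labels from C57BL/6 mice, with a stranded mRNA library kit on an Illumina instrument. The series' design text calls the samples of a group biological replicates. The authors deposited a table of counts per gene, whole numbers that were not normalized, with 43432 Ensembl gene identifiers. Per the submitters' processing notes, STAR and the mouse build GRCm38 were used. The counting tool, its strand setting and the annotation release are not given in the sources used here, so genes that overlap on either strand, and near-identical copies such as Hspa1a and Hspa1b, the Tcrg constant genes, H2 class I genes and Hba genes, have uncertain counts. Symbols, positions and biotypes came from GENCODE M21 on GRCm38, in which 42548 of the identifiers were found.

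WT replicate 1 carries 1 floxed Ezh2 allele per its label and was kept in the WT group as its label states. Libraries were compared for duplicates by chi-square over genes, and the lowest value per degree of freedom was 21.9, so each counted as its own replicate. Total counts were 36048198, 43962087, 33718125 and 62201921 in Ezh2-deficient replicates 1 to 4 and 59796319, 32469450, 33889010, 36867594 and 53353348 in WT replicates 1 to 5. Genes with a count numbered 17031 to 17948 and 17694 to 18500 per library, and mitochondrially encoded transcripts took 1.07 to 1.42% of counts. Reads were not marked by molecular identifiers, so intervals cover counting error only.

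Of 22839 genes with a count, 13685 passed edgeR's default filter on low counts. Library sizes were scaled by trimmed means of M-values, and genes were tested with edgeR's robust quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3), where the biological coefficient of variation was 0.206. All adjusted p values of genes are Benjamini-Hochberg values of this two-sided test with a threshold of 0.05 unless another tool is named. Levels are CPM, counts scaled to library size with those factors, given as mean ± SD over n = 4 Ezh2-deficient and n = 5 WT libraries, and log2 fold changes are Ezh2-deficient over WT. Ratios of genes with 1 to 3 WT counts have exact 95% intervals from the counts. Principal components used log2 CPM with a prior count of 2.

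The comparison, its tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were 16 fixed genes, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM in a group and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Predicted and clone-named genes and antigen receptor variable segments were left out of the rises and falls. Of 37 gene lists, 36 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. The lists covered PRC2, PRC1, cell cycle inhibitors, developmental transcription factors, Treg, effector Treg, naive, helper, cytokine, chemokine, receptor, signalling, cell cycle, p53, apoptosis, interferon, MHC, metabolic and adhesion genes, markers of other cells, and sex-linked, mitochondrial and histone transcripts. List members given with values that are outside the named-gene rule, such as Trp53, Bax, Isg15, Irf7 and Sesn2, were chosen after their values were seen. Results of some genes are not reported here.

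Alternatives were relative log expression, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom without and with quality weights, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change and, for principal components, the 500 most variable genes. Chosen after the data were examined were sex or a hypoxia score as a covariate, 1 surrogate variable (sva 3.50.0), the high or the low hypoxia score libraries only, leaving out the library with the highest Cd8a of each group, and leaving out genes within 20 Mb of Ezh2.

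The test was tried on simulated counts over 13618 genes, with gene means pooled over these 9 libraries and the depth of each library. Of genes changed 1.5-fold, 2-fold and 4-fold, edgeR called 28 of 67, 43 of 67 and 55 of 66, all with the right sign, and 6 of its calls were false. Only 200 genes were changed there, whereas 3001 (21.9%) passed in the data. The Benjamini-Hochberg cut-off on p was therefore stricter in the simulation, and these shares do not measure the sensitivity of this comparison. Camera called 0 of 35 lists that had not been shifted. The simulated genes varied independently of each other. This therefore does not test camera on lists whose members vary together, such as the G1/S genes (estimated correlation 0.644) and the cholesterol synthesis genes (0.592). List tests were run with edgeR's and limma's functions, and DESeq2 was used for single genes.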

Results

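Gene expression was measured by RNA sequencing in mouse regulatory T cells (Tregs), the CD4 T cells that express the transcription factor Foxp3 and restrain immune responses. Cells were sorted by surface markers, stimulated through CD3 and CD28 on beads, and grown with 2000 U/ml interleukin-2 until day 4. The 4 Ezh2-deficient libraries came from mice with both Ezh2 alleles floxed and a Cre recombinase driven by Foxp3, and the 5 WT libraries from mice with the same Cre. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 and holds genes silent. Total counts were 33718125 to 62201921 per Ezh2-deficient library and 32469450 to 59796319 per WT library, and 13685 genes were tested. Correlations of log2 expression across genes, which are not independent replicates, were 0.972 to 0.986 between Ezh2-deficient libraries, 0.979 to 0.987 between WT libraries and 0.95 to 0.973 between the groups. The first principal component, with 43.6% of the variance, placed all 4 Ezh2-deficient libraries below all 5 WT libraries.

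The comparison asked how transcripts of activated Tregs differ when Ezh2 is lost. Ezh2 itself (ENSMUSG00000029687; GRCm38 chromosome 6, 47530139 to 47595341, protein coding) was at 153, 167, 164 and 159 CPM (counts scaled to library size) in Ezh2-deficient replicates 1 to 4. The WT replicates 1 to 5 were at 268, 332, 288, 234 and 360 CPM. The means were 161 ± 6.49 CPM (SD, n = 4) and 296 ± 50.5 CPM (SD, n = 5), a 1.84-fold lower level (log2 fold change -0.88, SE 0.11, adjusted p = 0.000363), with every Ezh2-deficient library below every WT library. WT replicate 1, labelled with 1 floxed and 1 wild-type allele, lay within the range of the other 4, and the change without it was -0.93 (adjusted p = 0.000664; 9.51e-11 to 0.0211 over all alternatives). These are sums over the whole gene, and the floxed exons were not named, so transcripts that lack only those exons are still counted. The closest relative, Ezh1, was at 92.7 ± 7.37 against 78.7 ± 9.33 CPM and did not pass the test (log2 fold change 0.24, adjusted p = 0.0974).

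**Figure D1:**
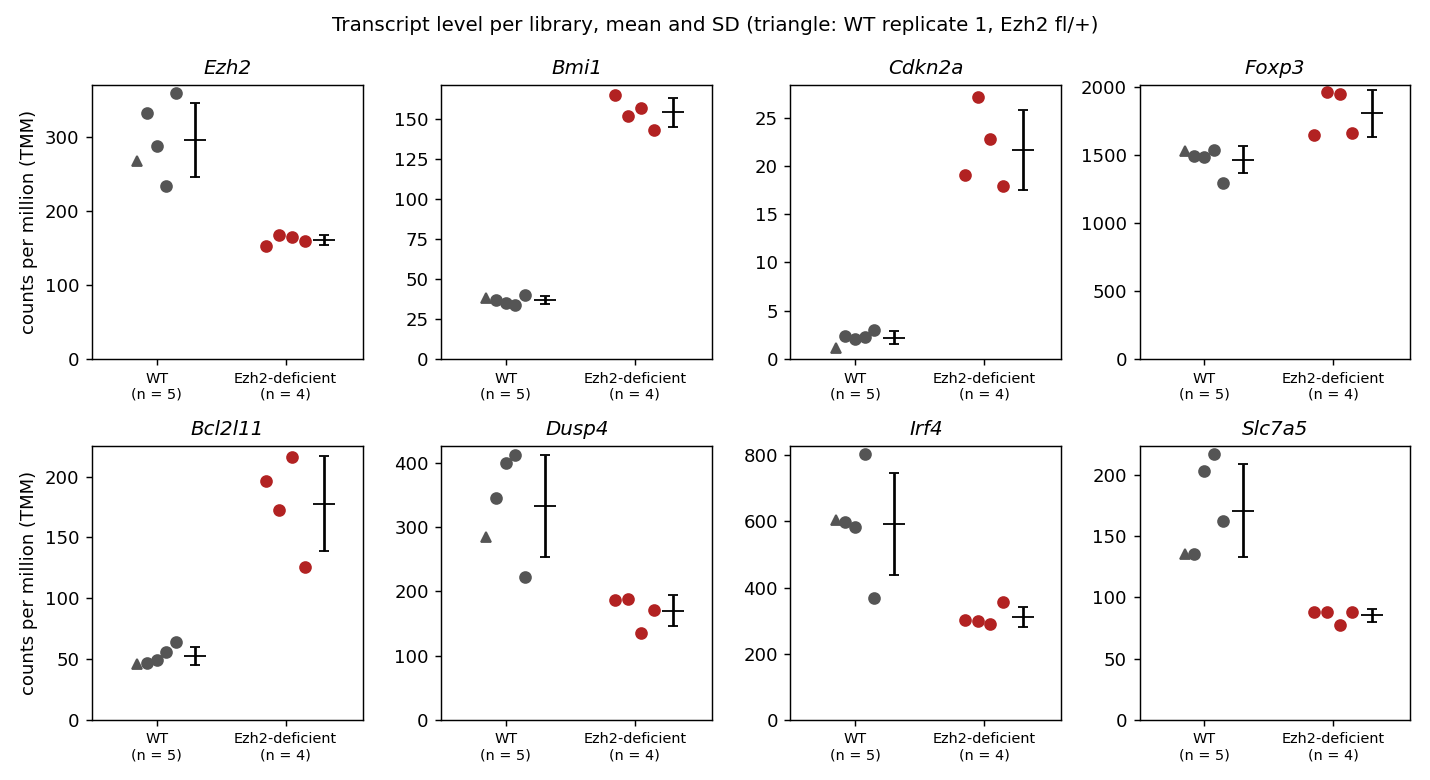
CPM (vertical axes, from 0, each gene with its own scale) of 8 genes in each library, with the mean and SD of each group beside the points (n = 5 WT, n = 4 Ezh2-deficient; the triangle is WT replicate 1). All 4 Ezh2-deficient libraries lie below the WT libraries for Ezh2 (153 to 167 against 234 to 360 CPM), and all 4 lie above them for Bmi1 (143 to 164 against 33.7 to 39.8 CPM).

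Ezh2-deficient Tregs expressed the cell cycle inhibitor gene Cdkn2a 9.89-fold higher and the Polycomb gene Bmi1 4.19-fold higher than WT Tregs, and expressed genes that were nearly absent from WT cells, such as Gda, Calca and Kirrel. Of the p53 target genes 16 of 26 rose, and of the interferon-stimulated genes 14 of 46, whereas 14 of 24 cholesterol synthesis genes and 16 of 28 amino acid stress genes fell. These 4 lists passed camera, but not with the correlation estimated from the data (adjusted p = 0.24, 0.37, 0.47 and 0.37 with an estimated correlation). Irf4, Dusp4, Tgfb1 and Ccr6 fell. The transcripts of Il2ra, Ctla4, Ikzf2 and Gata3 did not pass the test. Among the 13685 genes tested, 3001 (21.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1797 higher and 1204 lower. At 2-fold or more the numbers were 655 higher and 182 lower, and at 4-fold or more 191 and 38. The groups did not overlap for 2387 of the 3001 genes, and 21.2% of all tested genes did not overlap, where chance gives 1.59%. The rises of 2-fold or more lay mostly among weakly expressed genes. In 5 classes of 2737 genes each, ordered from the lowest to the highest mean level, they numbered 266, 238, 79, 41 and 31, against 85, 70, 19, 6 and 2 falls of that size. The count was 1972 without Ezh2-deficient replicate 3. Libraries of both groups also differed in hypoxia-response transcripts, scored over 22 genes after the data had been examined, and the counts were 1764 within the 5 libraries with high and 570 within the 4 with low scores. The second principal component (17.3% of the variance) placed the 5 above the 4. The CD8 T cell gene Cd8a was at 28.3 to 97.6 CPM in the 5. It was at 0.361 to 1.98 CPM in the 4, except in WT replicate 5 (41.1 CPM).

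**Figure D2:**
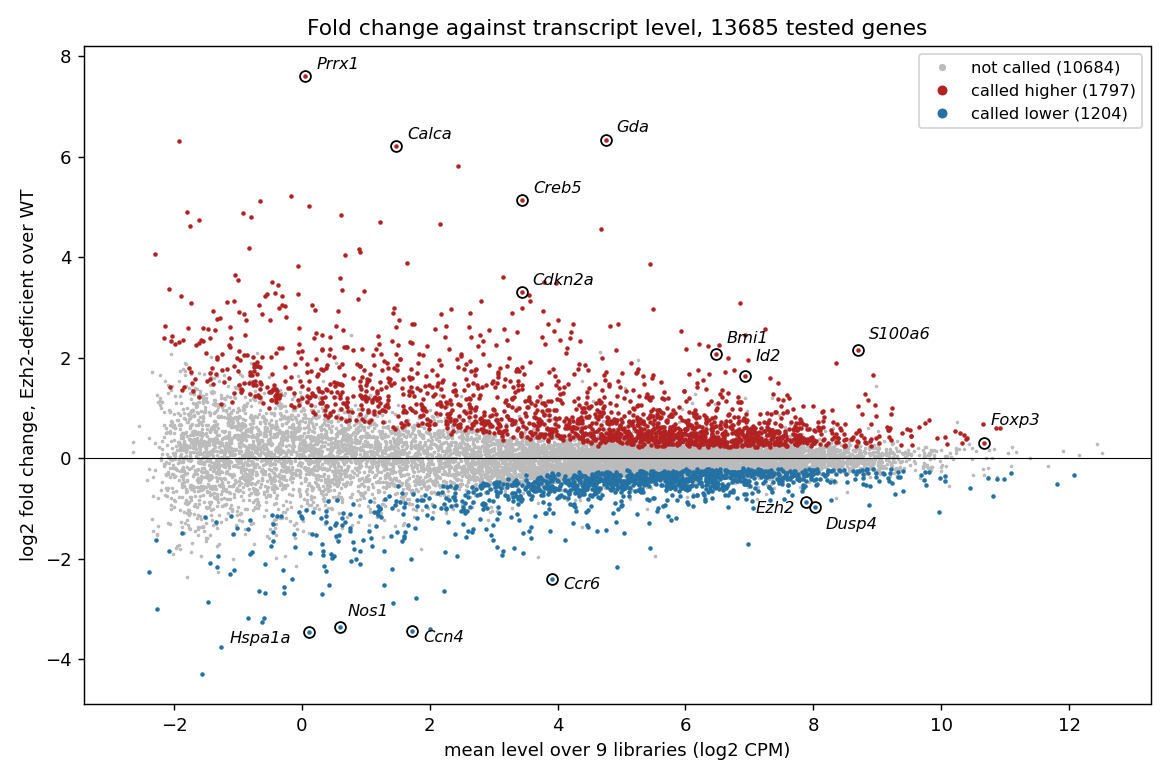
Log2 fold change of Ezh2-deficient over WT Tregs (vertical axis) against the mean level over the 9 libraries (horizontal axis, log2 CPM), where each point is a tested gene. The 1797 higher genes include Gda at 6.34 and Calca at 6.22, and the 1204 lower genes include Hspa1a at -3.46 and Ccn4 at -3.45.

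The 10 largest rises without overlap between the groups were in genes with little or no expression in WT Tregs. Prrx1, a homeobox gene of mesenchyme (chromosome 1, 163245119 to 163313710), had 418 counts in the Ezh2-deficient and 2 in the WT libraries, a ratio of 261 with a 95% counting interval of 71.9 to 2170. Gda, which encodes guanine deaminase (chromosome 19, 21391307 to 21473445), rose to 59.7 ± 7.22 CPM from 0.714 ± 0.544 (log2 fold change 6.34, SE 0.42, adjusted p = 2.46e-05). Calca, the gene of calcitonin and its related peptide, rose to 6.17 ± 2.16 from 0.0853 ± 0.106 CPM (log2 fold change 6.22, adjusted p = 6.01e-05). The others were Kirrel (log2 fold change 5.82), Mab21l1 (5.21), Creb5 (5.14), Upk1b (5.13), Onecut2 (5.03), Sirpa (4.88) and Foxq1 (4.81), with adjusted p from 0.000165 to 0.0246. Without WT replicate 5, which held both Prrx1 counts of the WT group, Kirrel was at 8.01, Mab21l1 at 6.48 and Foxq1 at 5.46, and without WT replicate 4 Calca was at 7.21, fitted values that rest on few counts in the remaining WT libraries. Creb5 lies on chromosome 6 like Ezh2 (53287270 to 53700376). It had 173 counts in WT replicate 1, which carries 1 floxed allele, and 0 or 1 in the other WT libraries. It no longer passed without Ezh2-deficient replicate 1, 3 or 4 (log2 fold change 5.06, 5.08 and 5.11; adjusted p = 0.0578, 0.0598 and 0.0511, at most 0.158 over all alternatives), and was at 11.31 without WT replicate 1, a fitted value that rests on 1 count in the other 4 WT libraries.

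The 10 largest falls were smaller and also in weakly expressed genes. Hspa1a, a stress-induced HSP70 gene (chromosome 17, 34969190 to 34972156), fell to 0.162 ± 0.0349 CPM from 1.82 ± 1.55 (log2 fold change -3.46, SE 0.65, adjusted p = 0.00329), and may share reads with its near-identical neighbour Hspa1b. Ccn4, a Wnt-induced matrix protein gene (chromosome 15, 66891320 to 66923201), fell to 0.487 ± 0.274 from 5.55 ± 3 CPM (log2 fold change -3.45, adjusted p = 0.00082). The nitric oxide synthase gene Nos1 fell to 0.253 ± 0.133 from 2.52 ± 0.537 CPM (log2 fold change -3.35, adjusted p = 0.000183). Maats1 (-3.40), Fam217b (-3.26), Cblc (-3.19), Ccdc33 (-2.88), Avpr1a (-2.78), Slc22a2 (-2.69) and Ly6d (-2.65) made up the 10, with adjusted p from 0.000471 to 0.0144. Without Ezh2-deficient replicate 4 Fam217b was at -4.11 and Avpr1a at -3.69, without Ezh2-deficient replicate 2 Slc22a2 was at -3.31, and without WT replicate 4 Hspa1a was at -2.81.

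Of 7 cell cycle inhibitor genes at loci known to be bound by PRC2, 4 rose and 0 fell, and 4 rose adjusted over the list alone (camera adjusted p = 7.2e-05; adjusted p = 0.094 with an estimated correlation). Cdkn2a (ENSMUSG00000044303; chromosome 4, 89274471 to 89294653), which encodes p16 and p19Arf from transcripts that these counts do not separate, was at 21.7 ± 4.14 against 2.20 ± 0.68 CPM (log2 fold change 3.31, SE 0.24, adjusted p = 7.44e-06). Its neighbour Cdkn2b rose by a log2 fold change of 1.92, Cdkn1c by 1.19 and Cdkn1a, also on the p53 list, by 1.03 (adjusted p = 0.000282, 0.00675 and 0.00108), whereas Cdkn2c (0.26), Cdkn2d (-0.14) and Cdkn1b (-0.03) did not pass. Most homeobox and developmental transcription factor genes were too low to be tested: of 99, 8 were, of which 3 rose and 0 fell (5 and 1 adjusted over the list alone). Their median log2 fold change was 1.40 (camera adjusted p = 0.000235; adjusted p = 0.24 with an estimated correlation). Irx2 rose to 3.34 ± 0.894 from 0.203 ± 0.107 CPM (log2 fold change 4.05, adjusted p = 4.03e-05), Lhx2 rose by 1.04 (adjusted p = 0.00573), and Zic1 had 101 counts against 1, a ratio of 126 (95% counting interval 22.2 to 5040), where the 1 count was in WT replicate 5.

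Among Polycomb genes, Bmi1, a subunit of PRC1 known to repress the Cdkn2a locus, had the smallest adjusted p of all the named genes. Bmi1 (ENSMUSG00000026739; chromosome 2, 18677018 to 18686629) rose to 154 ± 8.93 from 36.7 ± 2.45 CPM (log2 fold change 2.07, SE 0.08, adjusted p = 4.06e-08). Of 22 PRC1 subunits and H3K27 demethylases, 4 rose and 3 fell (6 and 3 adjusted over the list alone). As a list they did not pass camera (adjusted p = 0.498), whereas fry passed them upward (fry adjusted p = 0.0365). Rnf2, the E3 ligase of PRC1, rose by a log2 fold change of 0.49 and Pcgf6 fell by 0.54 (adjusted p = 0.00141 and 0.00196). Of 12 PRC2 subunits, 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.223), namely Ezh2 and Rbbp7, which fell by 0.32 (adjusted p = 0.0168). At an unadjusted p under 0.05, 4 PRC2 subunits differed, and DESeq2 and limma-voom each called 2.

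**Figure D3:**
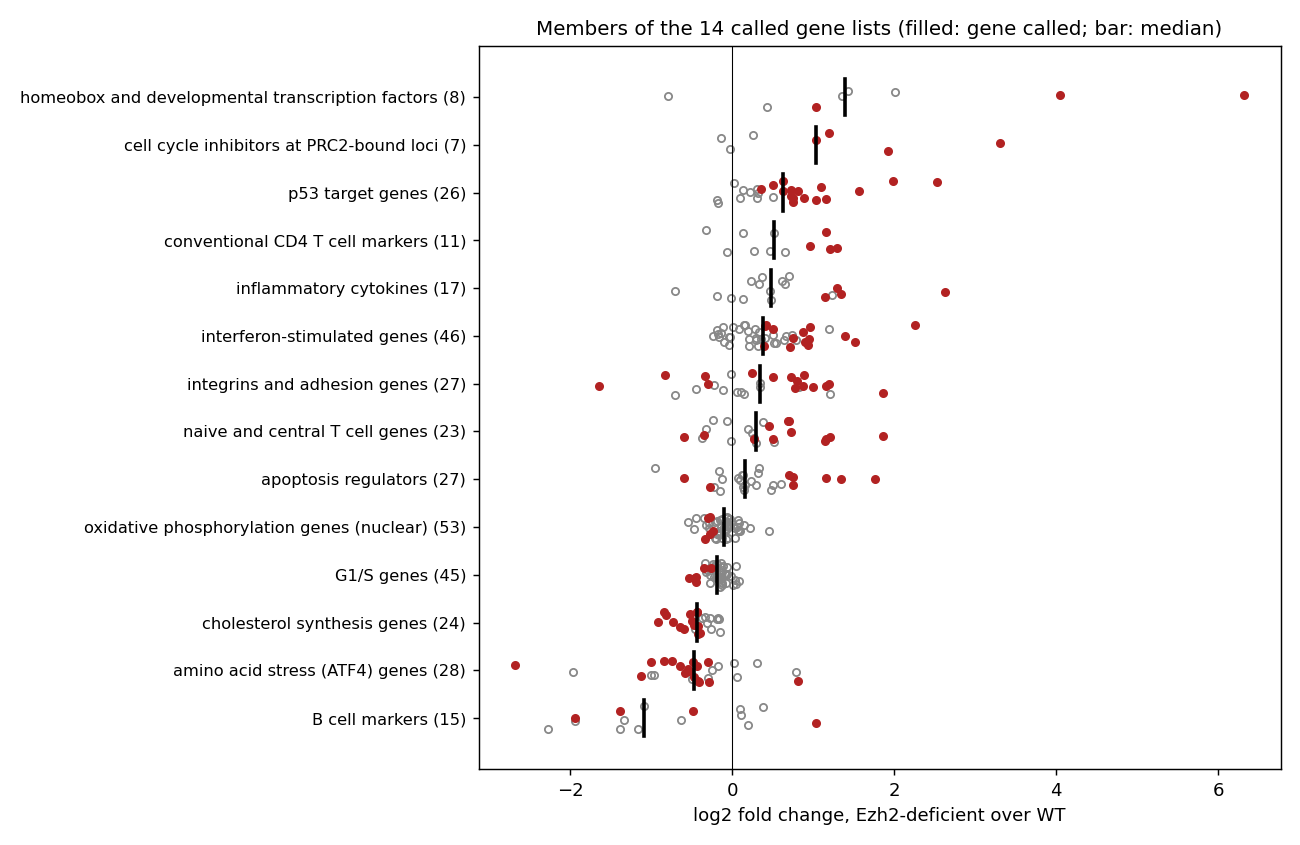
Log2 fold change (horizontal axis) of each tested member of the 14 gene lists that passed camera, with the number of members in brackets, filled points for genes that passed the test and a bar at the median. The medians run from 1.40 for developmental transcription factors to -1.09 for B cell markers.

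Foxp3 was at 1808 ± 176 CPM in Ezh2-deficient and 1469 ± 101 CPM in WT Tregs, 1.23-fold higher (log2 fold change 0.30, SE 0.09, adjusted p = 0.0313) and higher in 4 of 4 libraries. This call did not hold without Ezh2-deficient replicate 1, 2 or 3 (log2 fold change 0.32, 0.23 and 0.24) or WT replicate 2, 3 or 5 (0.28, 0.28 and 0.24), with adjusted p from 0.0503 to 0.126. Over all alternatives the change was 0.12 to 0.47, with an adjusted p of up to 0.461, and it also missed the threshold within the high and within the low hypoxia score libraries. The gene overlaps Flicr and the antisense genes Ccdc22 and Ppp1r3f. Il2ra (6108 ± 534 against 5649 ± 344 CPM, adjusted p = 0.361), Ctla4 (982 ± 204 against 872 ± 87.7, adjusted p = 0.359) and Ikzf2 (468 ± 70.7 against 431 ± 74.6, adjusted p = 0.555) did not pass. Of the 36 genes of the Treg signature, 8 rose and 7 fell (8 and 8 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.646). Its median of 0.05 and mean of -0.06 differed in sign. Il2rb, the interleukin-2 receptor beta chain, rose to 2281 ± 57.5 from 1508 ± 186 CPM (log2 fold change 0.60, adjusted p = 0.0013). The actin-capping gene Capg fell by 0.66, the phosphatase gene Dusp4 by 0.97 and Tgfb1 by 0.59 (adjusted p = 0.000844, 0.00308 and 0.00407). Il10 was at 4.24 ± 4.95 against 10.2 ± 3.63 CPM (log2 fold change -1.24, adjusted p = 0.211). Ezh2-deficient replicate 4, which also had the highest Cd8a of its group at 79.9 CPM, stood at 11.6 CPM, and without it the Il10 change was -2.53 (adjusted p = 0.00118; 0.00118 to 0.437 over all alternatives). The fall of Il10 passed in 8 of 24 alternatives, among them that fit and limma-voom without and with quality weights, and missed the threshold in the other 16.

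Genes of effector Tregs moved both ways. Of 24, 5 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.223), with a median of -0.03 and a mean of 0.24. S100a4 rose to 283 ± 53.2 from 47.5 ± 16.3 CPM and S100a6 to 730 ± 96.1 from 164 ± 74 CPM (log2 fold change 2.57 and 2.16; adjusted p = 0.000165 and 0.00127). The helix-loop-helix inhibitor gene Id2 rose to 196 ± 20.1 from 62.7 ± 12.3 CPM (log2 fold change 1.64, adjusted p = 3.34e-05), while Irf4, a transcription factor of effector Tregs, fell to 312 ± 30.2 from 592 ± 154 CPM (log2 fold change -0.92, adjusted p = 0.00404). Genes of naive and central T cells passed as a list: of 23, 10 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.29, camera adjusted p = 0.00145; adjusted p = 0.37 with an estimated correlation). Id3, Satb1, Il6st and Txk rose by log2 fold changes of 1.21, 1.16, 0.73 and 0.69 (adjusted p = 8.07e-05 to 0.00161). Markers of conventional CD4 T cells, most of which are also on other lists, rose for 4 and fell for 0 of 11 (5 and 0 adjusted over the list alone; median 0.52, camera adjusted p = 0.00186; adjusted p = 0.37 with an estimated correlation). The 4 were Id3 and Satb1 of the naive list, Tnfsf8 of the cytokine list, and Pde3b, while Il2, Cd40lg and Tcf7 did not pass (0.47, 0.13 and -0.06). Pde3b lost its call without Ezh2-deficient replicate 1, 3 or 4 or WT replicate 1, 2, 3 or 5 (log2 fold change 0.69 to 1, adjusted p = 0.0511 to 0.115, at most 0.287 over all alternatives).

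Helper lineage genes did not pass camera as lists, although single members changed, and fry passed the T helper 2 list upward (adjusted p = 0.0388). Of 31 T helper 1 and cytotoxic genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0667). Among them Stat4, the interleukin-18 receptor gene Il18r1 and the granzyme gene Gzmc rose (log2 fold change 0.97, 1.27 and 1.58; adjusted p = 0.000141, 0.0016 and 0.00599), while Ifng stayed near the floor at 0.369 ± 0.149 against 0.239 ± 0.162 CPM (adjusted p = 0.398). Tbx21 was at 1.25 ± 1.35 against 1.87 ± 0.83 CPM (log2 fold change -0.55, adjusted p = 0.529), and at -1.70 without Ezh2-deficient replicate 4 (adjusted p = 0.0249; 0.0249 to 0.865 over all alternatives). Of 17 T helper 2 genes, 4 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.327). Gfi1 rose by a log2 fold change of 1, Ccr4 fell by 0.55 (adjusted p = 0.000193 and 0.0118), and Gata3 was equal within error at 76.3 ± 13.3 against 75.2 ± 13.7 CPM (adjusted p = 0.94). Of 18 T helper 17 genes, 4 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.498). The chemokine receptor gene Ccr6 fell to 4.44 ± 1.91 from 23.7 ± 10.6 CPM (log2 fold change -2.40, adjusted p = 0.00248). In the opposite direction, the overlapping genes Tmem176a and Tmem176b, both near Ezh2 on chromosome 6, rose by 2.52 and 2.63 (adjusted p = 8.32e-05 and 9.42e-05). Of 12 T follicular helper genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.969), among them Slamf6 and Angptl2, which fell by 0.72 and 1.63 (adjusted p = 0.00356 and 0.0107). Il4 and Il17a were too low to be tested, with 27 and 23 counts in the Ezh2-deficient and 9 and 3 in the WT libraries, and all 23 Il17a counts were in replicate 4.

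Of 17 inflammatory cytokine genes, 4 rose and 0 fell (the same adjusted over the list alone; median 0.48, camera adjusted p = 0.00469; adjusted p = 0.37 with an estimated correlation). Within the high hypoxia score libraries the list's median was 0.19 and its call was lost (adjusted p = 0.124). Tnfsf8, the gene of CD30 ligand, rose to 152 ± 44.4 from 61.9 ± 4.74 CPM, Tnfsf11, which encodes RANKL, to 50.3 ± 3.75 from 22.9 ± 3.89, and Fasl, also on the apoptosis and T helper 1 lists, to 7.94 ± 1.64 from 3.14 ± 0.907 (log2 fold change 1.29, 1.14 and 1.34; adjusted p = 0.000363, 0.000146 and 0.00259). Csf2 stayed under 1 CPM (log2 fold change 2.63, adjusted p = 0.029) and lost its call without Ezh2-deficient replicate 2 or 3 (2.38 and 2.53; adjusted p = 0.0661 and 0.07, at most 0.23 over all alternatives). Tnf (77.9 ± 7.48 against 60 ± 20.3 CPM, adjusted p = 0.226) and Il2 (0.377 ± 0.047 against 0.261 ± 0.157 CPM, adjusted p = 0.485) did not pass. Of 25 chemokine and chemokine receptor genes, 3 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.842), with Cx3cr1 up by a log2 fold change of 1.73 (adjusted p = 0.000307). Of 18 inhibitory receptor genes, 2 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.724). Cd274, the gene of PD-L1, and Cd96 rose by 0.84 and 0.43 (adjusted p = 0.000909 and 0.0054). Tigit fell by 1.14 (adjusted p = 0.0254) but lost its call without Ezh2-deficient replicate 1 or 2 (-1.19 and -1.08; adjusted p = 0.0576 and 0.0587, at most 0.0926 over all alternatives).

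Genes induced by p53 made up the list with the smallest camera p. Of 26, 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.63, camera adjusted p = 4.14e-10; adjusted p = 0.24 with an estimated correlation). Perp rose to 28.6 ± 1.56 from 4.92 ± 1.92 CPM (log2 fold change 2.53, SE 0.22, adjusted p = 3.52e-05), the death receptor gene Fas to 62.8 ± 7.79 from 28.2 ± 3.53 CPM (log2 fold change 1.16, adjusted p = 6.68e-05), and Sesn1 and Plk2 rose by 0.89 and 1.56 (adjusted p = 0.000426 and 0.000709). Trp53 itself did not pass (-0.17, adjusted p = 0.287), nor did Bax (0.10, adjusted p = 0.689). Apoptosis regulators, which share Fas, Pmaip1, Tnfrsf10b, Bbc3 and Bax with that list, rose for 6 and fell for 2 of 27 (8 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 0.0168; adjusted p = 0.24 with an estimated correlation). Bcl2l11, the gene of the pro-apoptotic protein Bim, rose to 178 ± 39.1 from 52.3 ± 7.57 CPM (log2 fold change 1.76, adjusted p = 3.45e-05). The anti-apoptotic gene Bcl2, also on the naive and STAT5 lists, rose by 0.70 (adjusted p = 0.0162), a call lost without Ezh2-deficient replicate 1 or 4 (0.58 and 0.60; adjusted p = 0.0656 and 0.0561, at most 0.0813 over all alternatives).

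Of 45 G1/S genes, 0 rose and 6 fell (0 and 4 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.000674; adjusted p = 0.79 with an estimated correlation, and 0.191 with fry). Cyclin E1, encoded by Ccne1, fell by a log2 fold change of 0.53, and Exo1 and Uhrf1 each fell by 0.45 (adjusted p = 0.00256, 0.0179 and 0.0198). Of 52 G2/M genes, 1 rose and 2 fell, and 0 did adjusted over the list alone (camera adjusted p = 0.842). At an unadjusted p under 0.05, 5 differed, and DESeq2 and limma-voom each called 3. Aurkb fell by 0.35 (adjusted p = 0.0195). Of 9 replication-dependent histone genes and 6 sex-linked transcripts none passed in edgeR, at an unadjusted p under 0.05, or in DESeq2 or limma-voom, with 0 calls each (camera adjusted p = 0.988 and 0.984). Each group held both sexes (Xist at 2.63 to 3260 CPM in Ezh2-deficient and 0.316 to 2580 CPM in WT libraries), so the sex-linked result says little.

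Genes stimulated by interferon rose for 14 and fell for 0 of 46 (18 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 0.000126; adjusted p = 0.37 with an estimated correlation). Gbp4 rose to 165 ± 30.4 from 34.4 ± 11.6 CPM (log2 fold change 2.26, adjusted p = 0.000445), although it overlaps Gbp8 and Gbp9. Slfn1, Ifih1, which encodes the RNA sensor MDA5, and Slfn8 rose by 0.95, 0.93 and 0.75 (adjusted p = 0.000282, 0.000576 and 0.00137), while Isg15 (-0.17) and Irf7 (-0.14) did not pass. Of 25 major histocompatibility complex genes, 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.327). Nlrc5, a regulator of class I genes, rose to 388 ± 19.4 from 202 ± 57.5 CPM (log2 fold change 0.94, adjusted p = 0.00935), and H2-Oa and H2-DMa rose by 0.93 and 0.50 (adjusted p = 0.000628 and 0.00438). Cd74, the class II invariant chain, fell by 1 (adjusted p = 0.00655), in the direction of the B cell gene Cd79a, which fell by 1.38.

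Of 24 cholesterol synthesis genes, 0 rose and 14 fell (0 and 17 adjusted over the list alone; median -0.43, camera adjusted p = 2.39e-07; adjusted p = 0.47 with an estimated correlation). Tm7sf2, Mvd, Acat2 and Dhcr7 fell by log2 fold changes of 0.92, 0.82, 0.73 and 0.64 (adjusted p = 0.00343 to 0.00796). Genes of the amino acid stress response driven by the transcription factor ATF4 rose for 1 and fell for 16 of 28 (1 and 20 adjusted over the list alone; median -0.47, camera adjusted p = 4.16e-07; adjusted p = 0.37 with an estimated correlation). Slc7a5, the large neutral amino acid transporter, fell to 85.5 ± 5.24 from 171 ± 38 CPM (log2 fold change -1, SE 0.14, adjusted p = 0.000701). Slc7a1, Aars and the serine synthesis gene Psat1 fell by 0.65, 0.58 and 0.53 (adjusted p = 0.00123, 0.000859 and 0.00092), and Sesn2, which is also a p53 target, rose by 0.81 (adjusted p = 0.00158). Of 53 nuclear genes of oxidative phosphorylation, 0 rose and 5 fell (camera adjusted p = 0.0211; adjusted p = 0.79 with an estimated correlation, 0.147 with fry and 0.0671 without Ezh2-deficient replicate 4, where the median was also -0.10; 0.072 without the highest Cd8a libraries). Adjusted over the list alone 0 fell. The median was -0.10, and Cyc1 fell by 0.34 (adjusted p = 0.0113). At an unadjusted p under 0.05, 12 differed, and DESeq2 and limma-voom each called 5. Of 24 glycolysis genes, 0 rose and 1 fell (the same adjusted over the list alone; median -0.37, camera adjusted p = 0.0667), namely Eno3, which fell by 1.71 (adjusted p = 0.00938). Of 9 mitochondrially encoded transcripts 0 passed in edgeR (0 adjusted over the list alone; camera adjusted p = 0.149), with 3 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma-voom.

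Signalling lists were mixed. Of 25 STAT5 and cytokine feedback genes, 5 rose and 2 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.961), with Stat5b lower by a log2 fold change of -0.33 (adjusted p = 0.00436). Of 31 T cell receptor activation genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.984). Of 22 AP-1 and stress response genes, 6 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.984). Nr4a2 rose by 1.82 and Ier5 by 0.73, and the chaperone gene Hsph1 fell by 0.58 (adjusted p = 0.00192, 0.00146 and 0.00562). Fosb was at 113 ± 65.3 against 19.5 ± 5.69 CPM (log2 fold change 2.54, adjusted p = 0.0188) and lost its call without Ezh2-deficient replicate 3 or WT replicate 3 (2.29 and 2.47; adjusted p = 0.0509 and 0.0539, at most 0.291 over all alternatives). Of 27 integrin and adhesion genes, 11 rose and 4 fell (the same adjusted over the list alone; median 0.34, camera adjusted p = 0.0296; adjusted p = 0.41 with an estimated correlation, and 0.139 without Ezh2-deficient replicate 4, where the median was 0.18). Without the highest Cd8a libraries its adjusted p was 0.0758, and within the low hypoxia score libraries 0.0769. Ly6c1 is on this and the naive list. The integrin beta 1 gene Itgb1 rose to 670 ± 123 from 301 ± 73.9 CPM (log2 fold change 1.16, adjusted p = 0.00158), and the tetraspanin gene Cd9, Itga5 and Cd44 rose by 0.89, 0.78 and 0.51 (adjusted p = 0.000271, 0.00671 and 0.00287).

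Of 15 B cell markers, 1 rose and 3 fell (the same adjusted over the list alone; median -1.09, camera adjusted p = 0.0211; adjusted p = 0.49 with an estimated correlation, and 0.0527 without WT replicate 3, where the median was -1.06). The call was also lost within the high hypoxia score libraries (median -0.27, adjusted p = 0.129) and under the strict filter (median -0.78, adjusted p = 0.156). Ighm, the immunoglobulin mu constant gene, was at 491 ± 61.7 against 690.5 ± 116 CPM (log2 fold change -0.49, adjusted p = 0.0187), a call lost without Ezh2-deficient replicate 1 (-0.43, adjusted p = 0.0522, at most 0.134 over all alternatives). Cd79a fell to 0.885 ± 0.329 from 2.33 ± 0.462 CPM (adjusted p = 0.00716). Cd8a ranged from 0.361 to 79.9 CPM in Ezh2-deficient and from 1.98 to 97.6 CPM in WT libraries, where Cd4 was at 392 to 434 and 450 to 487 CPM. Of 10 CD8 T cell markers, 1 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.969). That gene, Crtam, lost its call without Ezh2-deficient replicate 4 (log2 fold change 1.95 with it, and 1.04 without it, adjusted p = 0.11, at most 0.351 over all alternatives). Of 7 markers of NK, innate lymphoid and gamma-delta T cells, 3 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.116). These were the T cell receptor gamma constant genes Tcrg-C1, Tcrg-C2 and Tcrg-C4 (log2 fold change 2.42, 2.10 and 1.46; adjusted p = 0.00415, 6.47e-05 and 0.00287), whose similar sequences can exchange reads. Of 7 myeloid markers, 2 rose and 0 fell (the same adjusted over the list alone; camera adjusted p = 0.513), namely Adgre1 and Itgam (1.75 and 0.80; adjusted p = 0.00515 and 0.00817). Of 3 erythroid and platelet genes, too few for camera, 1 rose (3 adjusted over the list alone). It was Hba-a1, which was at 5.66 ± 3.63 against 1.72 ± 0.902 CPM (log2 fold change 1.70, adjusted p = 0.0245) and lost its call without Ezh2-deficient replicate 2 or WT replicate 2 or 3 (1.15, 1.59 and 1.74; adjusted p = 0.0736, 0.0565 and 0.0505, at most 0.0946 over all alternatives). Libraries without the highest Cd8a of each group gave 2006 genes, 1343 higher and 663 lower.

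In all, 14 of the 36 lists tested passed camera, 9 upward and 5 downward. With the correlation estimated from the data 0 passed (smallest adjusted p = 0.094, and 4 at an unadjusted p under 0.05). Correlated members cannot account for all of this. For the cell cycle inhibitor list the estimate was 0.003, under the preset 0.01, yet camera's unadjusted p rose from 8e-06 to 0.0026. For apoptosis regulators, also at 0.003, it rose from 0.00512 to 0.019. Fry, which does not compare a list with other genes, passed 17, of which 12 were among the 14. The others were PRC2 subunits (downward, fry adjusted p = 0.0365) and, upward, the PRC1 (0.0365), T helper 2 (0.0388), myeloid (0.0127) and NK (0.0224) lists. For 9 lists, of which 0 were among the 14, the median or the mean had the opposite sign to camera's direction: the Treg signature, effector Treg, T follicular helper (median 0.05, mean -0.15), chemokine (0.19, -0.06), STAT5 (0.06, -0.08), T cell receptor activation (-0.01, 0.21), G2/M (0.03, 0.01), CD8 (0.02, 0.24) and sex-linked (-0.23, 0.15) lists.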

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

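Of the tests here, the sex and hypoxia covariates, the fits without the highest Cd8a libraries, the placement of changed genes near Ezh2 and the G2/M median were chosen only after the results were seen.

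In 25 of 284 groups of library values, the gap between 1 library and the nearest of the others took an unusually large share of the group's range. For normally distributed values chance gives about 1 in 20. Some of these groups are CPM values near 0 that need not follow that form, so 25 of 284 is not measured against chance. Among Ezh2-deficient libraries, replicate 4 stood apart for Il10 (share 0.84; 11.6 CPM against 1.08 to 2.76), Avpr1a (0.88; 1.8 against 0.331 to 0.507), Ccr6 (0.965; 7.3 against 3.4 to 3.54), Atf3 (0.843; 1.97 against 7.16 to 8.13) and Crtam (0.855; 2.03 against 0.395 to 0.632). Replicate 2 did for Cdkn1c (0.863; 4.13 against 2.51 to 2.73) and Eno3 (0.924; 79.9 against 45.9 to 48.5). Replicate 3 did for Slc7a5 (0.98; 77.7 against 88.1 to 88.3) and Tcrg-C4 (0.835; 18.2 against 8.39 to 10).

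Among WT libraries, replicate 5 stood apart for Foxp3 (share 0.778; 1290 CPM against 1490 to 1540), Kirrel (0.879; 0.767 against 0 to 0.0926), Satb1 (0.757; 184 against 94.1 to 116) and Plk2 (0.777; 23 against 11.3 to 13.9). It alone had counts of Prrx1 and Zic1 (0.0374 and 0.0187 CPM against 0), where the share is always 1 because all the others are at 0. Replicate 1 stood apart for Creb5 (0.994; 2.93 against 0 to 0.0187), Gadd45g (0.739; 52.1 against 21.5 to 29.5), Fosb (0.812; 29.5 against 15.2 to 17.9) and Ifih1 (0.872; 8.51 against 9.86 to 10.1). Replicate 3 did for Cd44 (0.887; 119 against 136 to 139), Nlrc5 (0.719; 102 against 206 to 246), Atp5a1 (0.775; 1080 against 924 to 960) and Aars (0.746; 218 against 171 to 183). Replicate 4 did for Hspa1a (0.72; 4.47 against 0.374 to 1.52) and Itga5 (0.72; 9.15 against 15.6 to 18.1).

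The first pattern weighed was the 3001 genes that passed between the groups. Of 100 splits drawn from the 126 of the 9 libraries into 4 and 5, 1 called as many genes, the real one, and the highest other called 1336. That other split set WT replicates 1 to 4 against the remaining libraries, so it held most of the real difference. The result argues against chance but does not exclude it, since 1 in 100 is the smallest share these splits can give. With sex as a covariate 2490 of the 3001 genes still passed, and with the hypoxia score 2995 did. Sex was not a label but was read from Xist and Ddx3y, and each group held both sexes. The mean hypoxia score was -0.0525 in Ezh2-deficient and 0.044 in WT libraries. Covariates so alike between the groups could hardly take up the difference, so the refits test little. That likeness itself argues against either as the whole cause. Loss of Ezh2 may account for the pattern, as a hypothesis, and effects of rearing or culture that go with genotype were not tested.

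The second was that genes within 20 Mb of Ezh2 on chromosome 6 passed more often (53 of 209, 25.4%) than genes elsewhere (21.9%). Chance placement stays open. A lower share was found in 75.1% of autosomal windows of that length and in 54.5% at 10 Mb (32 of 139), within what 95% of windows show. At 5 Mb (15 of 48) 96.3% of 187 windows had a lower share. Windows with few tested genes were left out of the comparison, by a limit that the 48 genes near Ezh2 would also have missed. The value at 5 Mb is therefore not a rank among all windows of that length and decides nothing. A segment carried with the floxed allele, or a lower Ezh2 dose, would move WT replicate 1, with 1 floxed allele, toward the Ezh2-deficient libraries. Its median position between the other WT libraries (0) and the Ezh2-deficient mean (1) was 0.109 near Ezh2 and 0.217 elsewhere, both inside the range of the other WT replicates (-0.249 to 0.235 and -0.257 to 0.268). A margin of their SD (0.201 and 0.233), added after these values were seen, left both explanations open where the first form of the test had counted against them, so they cannot be told apart with 1 such library. These positions were taken on log2 CPM with a prior count of 2. Single genes near Ezh2 spread widely, with Gprin3 at 0.74, Creb5 at 0.66 and Chn2 at -1.91. Creb5 was at 2.93 CPM in WT replicate 1, 0 to 0.02 in the other WT libraries and 18.6 to 27 in Ezh2-deficient libraries. Its 0.66 is therefore not a share of the Ezh2-deficient CPM level. A median can hide such genes, so an effect of the segment on single genes stays open.

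The third was that 16 of 26 p53 target genes rose while 14 of 24 cholesterol and 16 of 28 amino acid stress genes fell, in lists whose camera calls were lost with an estimated correlation (adjusted p = 0.24, 0.47 and 0.37). With the hypoxia score as a covariate the lowest of the 3 list medians was at 100% of its value without it. The mean score was alike in the groups (-0.0525 in Ezh2-deficient and 0.044 in WT libraries), so the covariate could hardly move the medians. That likeness, rather than the refit, argues against this state as the whole cause. Leaving out the highest Cd8a libraries left the lowest of the 3 list medians at 91.6%, but the ratio of mean Cd8a in WT over Ezh2-deficient libraries rose from 1.55 to 2.91, so this decides nothing and other cells in the cultures stay open. Except for WT replicate 5, libraries with a low hypoxia score also had little Cd8a, so the hypoxia score and other cells are hard to tell apart here. Fewer cycling cells would lower G2/M genes, whose median was 0.03, with 49 of 52 within 0.3 of 0, which argues against this as the whole cause, although the G1/S median of -0.19 (6 of 45 fell; camera adjusted p = 0.000674, but 0.79 with an estimated correlation and 0.191 with fry) goes with it. An effect of Ezh2 loss also stays open, as a hypothesis.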

How the results depend on the processing

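The covariates, surrogate variable, hypoxia score subsets and the fits without the highest Cd8a libraries or genes near Ezh2 were chosen only after the results were seen. Genes passing numbered 3054, 3049 and 3128 with other scalings, 2813 and 2901 with other filters, 3881 with DESeq2, 2988 and 3325 with limma-voom, and of the 3001 genes, of which 2802 to 3001 were in each of the 24 refits compared, 0 changed sign. Leaving out 1 library gave 1972 (Ezh2-deficient replicate 3) to 3168 genes, 1170 to 1744 higher and 802 to 1477 lower; there were 1764 (1067 higher, 697 lower) in the high and 570 (424, 146) in the low hypoxia score libraries, where fewer libraries entered. Without the highest Cd8a libraries 663 were lower, with 1 surrogate variable 1837 were lower, and the cause was not tested. Without genes near Ezh2 2947 passed. Against a 1.5-fold change, a stricter hypothesis, 410 passed (362 higher, 48 lower). Ezh2 stayed lower in all alternatives (-0.99 to -0.80). Lists passing fell from 14 to 0 with an estimated correlation (smallest adjusted p = 0.094). The first component took 52.3% of variance with the 500 most variable genes and 45.5% without WT replicate 1, and the cause was not tested. Of genes that did not pass, Gata3 reversed to -0.01 with total counts only, to -0.01, -0.04 and -0.07 without Ezh2-deficient replicates 1, 2 and 3, to -0.02, -0.04 and -0.05 without WT replicates 1, 2 and 4, and to -0.09 in the low hypoxia score libraries. Ikzf2 reversed to 0 without Ezh2-deficient replicate 1 and to -0.16 in the low hypoxia score libraries, and Ctla4 to -0.03 there; the cause was not tested. Of 1210 results of named genes under planned settings other than leaving out a library, 1182 kept direction and side of the threshold, 24 lost and 3 gained a call; leaving out a library, 1142 of 1224 did, 73 lost and 2 gained a call. With the replicate number as a block 2767 genes passed (1590 higher, 1177 lower), 2345 of them shared. Same-numbered libraries correlated at 0.15, -0.08, 0.11 and 0.19, and 0 of 4 Ezh2-deficient libraries correlated best with its own number. The best correlations of replicates 1, 3 and 4 were only slightly higher, at 0.21, 0.16 and 0.22. Pairing by number was therefore not shown, and so few libraries cannot exclude it. The oxidative phosphorylation list was not called with the block (median -0.13, camera adjusted p = 0.0762). The developmental transcription factor list had too few genes for camera under the strict filter. What depth limits was not tested by thinning counts. At these depths, 28 of 67 simulated genes changed 1.5-fold and 43 of 67 changed 2-fold were called. Only 200 genes were changed in that simulation, so these shares do not measure what the comparison missed.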

Other observations

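The genes in these paragraphs, the test of neighbouring genes and its setting were chosen only after the results were seen.

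Among genes at 20 CPM or more that rose, Cacnb4, a calcium channel subunit gene, was at 54.7 ± 14.3 CPM (SD, n = 4), 23.5-fold above WT (edgeR log2 fold change 4.56, SE 0.28, adjusted p = 5.48e-06), and the glutamate decarboxylase gene Gad2 was at 23.4 ± 4.3 against 2.44 ± 2.27 CPM (SD, n = 5 for WT; 3.25, adjusted p = 0.00705). Cgnl1, a junction protein gene, reached 227 ± 88.5 from 26.3 ± 19.6 CPM, the stem cell factor receptor gene Kit 113 ± 43.8 from 25.1 ± 14.4 and Ms4a4b 552 ± 179 from 149 ± 72.7 (edgeR adjusted p = 0.00931, 0.00978 and 0.00534). Id1, of the same family as Id2 and Id3, rose by a log2 fold change of 3.52 (edgeR adjusted p = 3.45e-05).

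Among falls at that level, the transferrin receptor gene Tfrc was at 620 ± 88.7 against 1300 ± 239 CPM (edgeR log2 fold change -1.07, adjusted p = 0.000398) and Fut7, which makes selectin ligands, at 24 ± 2.19 against 58.3 ± 4.82 CPM (-1.28, adjusted p = 9.9e-06). Ncf1, of the NADPH oxidase, fell by 1.23 and Zbtb32 by 1.78 (edgeR adjusted p = 0.000445 and 0.0392). Beside the falls of Hspa1a and Hspa1b (-3.46 and -2.15), the heat shock genes Dnajb1 and Hspa8 were at -0.12 and -0.19 (edgeR adjusted p = 0.334 and 0.106).

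Genes that rose by 2-fold or more were often next to each other. Of 650 with a position, adjacent non-overlapping tested genes formed 67 pairs with both risen, against a mean of 26.9 and a highest of 50 in 10000 permutations within 5 classes of expression (p = 1e-04, the smallest they can give), which argues against chance placement of the genes as annotated. Examples were Cdkn2a and Cdkn2b, S100a4 and S100a6, and the Tcrg constant genes. Regulation of stretches of chromatin may account for it, as a hypothesis that was not tested, and related neighbours that share reads could add to the 67 pairs. Some pairs held predicted or clone-named genes, such as Gm37856 with Gm37469 and, overlapping Satb1, E430014B02Rik with C230085N15Rik. Whether these are separate transcripts was not tested, and the pairs without them were not compared with permutations.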
